A study of Mus musculus with 6 samples.

How the data were processed

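Gene expression was measured on 6 arrays of RNA from isolated pancreatic islets of male CD1 mice aged 8 weeks. Per the labels' protocols, the islets rested overnight in culture medium and then received vehicle (0.1% ethanol) or 200 uM CMPF for 24 hours. Total RNA was purified with a column kit, and biotin-labelled aRNA was made from 200 ng of it. The array is an Affymetrix mouse 3' expression array, on which a gene is read by 1 or more sets of short probes, mostly near the 3' end of its transcript.

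The deposited values are on a log2 scale and were made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects the background, forces all arrays to 1 distribution and summarises the probes of a set. It therefore removes differences in total signal between arrays and tends to compress differences of dim genes. The settings are not given in the sources used here. The median log2 value lay between 5.08 and 5.15 on the 6 arrays. The values carry no detection call, so a dim gene could not be told from an undetected one. The number of arrays limits the precision.

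The table held 45101 probe sets. The 64 control probe sets were left out, and 34945 of the others were listed with 1 gene, 932 with several genes and 9160 with none. Of those with 1 gene, 34741 matched a RefSeq gene table (GRCm38.p6) by Entrez ID, which changed 0 symbols, and 204 kept the platform's symbol. The array's annotation names no genome build, so no coordinates are given. Each of 18193 genes was represented by its single-gene probe set with the highest mean over the 6 arrays, and no filter on dim genes was applied. No value column lacked a sample.

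CMPF was compared with vehicle with the lmFit and eBayes functions of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All differences are CMPF minus vehicle in log2 units. Replicates are the samples the labels number 1 to 3 in each group. The labels do not say that the numbered samples came from separate animals or preparations, so p-values measure the spread between these samples, which may be technical.

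Before the data were examined, 32 gene lists (22 of pathways and 10 of cell type markers) were fixed with 649 member genes, of which 593 were measured. Each list was tested against all other genes with limma's camera at its preset correlation of 0.01, adjusted over the 32 lists. Camera with a correlation estimated per list, camera on ranks and the rotation test fry were alternatives. An estimated correlation also makes camera take its degrees of freedom from the arrays (4, or 2 with the block) and not from the genes. That setting therefore changes more than the correlation. Fry tests a list against no difference between the groups, not against other genes, so it asks another question than camera. The text names genes by a rule fixed at the same time. It takes the 10 genes with the largest difference in each direction past the threshold, with no overlap between groups and the higher group's mean above the median of all genes, filled up with genes of unadjusted p under 0.01. It adds the up to 4 members of each list with the smallest p, and 20 genes fixed by name, of which 16 were measured. The first part gave 0 genes, and the rest gave 139. The others fixed by name were not analysed here. Genes outside the rule are said to have been chosen after their values were seen.

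The replicate numbers were checked for pairing before fits were compared. Deviations from the group mean correlated between 0.488 and 0.638 for arrays of the same number, and between -0.555 and 0.0885 for arrays of different numbers in different groups. On 6 of 6 arrays the closest array of the other group had the same number. The numbers were therefore taken to pair the samples, from the data and not from a statement in the labels, and "pair" below means the vehicle and CMPF array of 1 number. A fit with the replicate number as a block was run beside the fit without it. It lowered the median standard error of a gene from 0.116 to 0.0877. Standard errors and intervals below are from the fit without the block unless stated, so they include the variation between pairs. No 2 arrays held identical values.

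The tests were tried on simulated data with the real genes' means and spreads, without pairing. For CMPF against vehicle, 200 of 18193 genes were changed at once, 50 by each size. Limma recovered 20% of genes changed by 0.5 log2 units and 80% of those changed by 1. It recovered 96% of those changed by 2 and 100% of those changed by 4, with 8 false calls. With so many true changes the adjustment is looser, so these rates overstate recovery where few genes change. Over 100 simulations with no change, camera at the preset correlation called 0.05 lists per simulation when genes were independent, and 15.45 of 32 when the members of a list shared a common factor as strong as their own noise. Such a factor is stronger than the correlation estimated in the pathway lists called below, from 0.026 (cholesterol) to 0.315 (ER chaperones). It is weaker than that estimated for acinar (0.784) and stellate (0.597) markers. Other alternatives were median centring, a second quantile normalization, the mean of a gene's probe sets, every probe set on its own, filters on dim genes, trend and robust priors, array weights, the acinar marker mean as a covariate, a minimum fold of 1.5, an adjusted p of 0.10 and leaving out each array. Leaving out each pair and combinations with the block were added after seeing the data. Leaving out 1 array keeps its partner, so differences between pairs then enter the comparison.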

Results

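Expression was profiled in isolated mouse pancreatic islets, the hormone-secreting cell clusters of the pancreas, after 24 hours with CMPF or with vehicle. CMPF (3-carboxy-4-methyl-5-propyl-2-furanpropanoic acid) is a furan fatty acid metabolite found in blood. The vehicle group and the CMPF group each held 3 arrays, and 18193 genes were tested. The series title names metabolism as the subject, so the comparison asks which metabolic and islet genes differ with CMPF. The log2 levels of any 2 arrays correlated across genes at 0.989 or more, where genes are not independent replicates. The log2 signal of the 3' Actb control exceeded that of the 5' control by 0.70 to 0.84 on all 6 arrays. For Gapdh this difference was -0.027, -0.089 and -0.045 with vehicle and 0.017, 0.017 and -0.016 with CMPF, higher with CMPF in all 3 pairs and without overlap between the groups.

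With CMPF, genes of the NRF2 antioxidant response, PPAR target genes, mitochondrial fatty acid oxidation genes and acinar cell markers lay higher as groups, and ER chaperones, cholesterol synthesis genes and stellate cell markers lay lower. All of these calls were lost with an estimated correlation (adjusted p = 0.907 for each list). The shifts of the pathway lists were small, with medians between -0.08 and 0.13. Islet hormone genes were not called and read close to the highest value on the arrays, so their small differences say little. No single gene passed the threshold: limma called 0 genes (smallest adjusted p = 0.99995), and 0 with the replicate block (smallest adjusted p = 0.979). An unadjusted limma p under 0.05 was reached by 205 genes, 133 higher and 72 lower with CMPF, and by 692 with the block. For independent arrays chance gives 909.65. The fit without the block counts variation between pairs as error, so that number is not an exact reference for its 205. The groups did not overlap for 822 genes (4.52%), where chance gives 10% for independent arrays; these arrays were paired, so that share is not an exact reference. The difference lay within 0.2 log2 units for 92.0% of genes, and 21 genes differed by at least 1.5-fold. The 10 genes with an unadjusted p under 0.01 all lay below the median level of all genes, so none met the brightness rule for naming.

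Of the 32 gene lists, camera at its preset correlation called 7, with 4 higher and 3 lower. All 7 calls were lost with an estimated correlation (adjusted p = 0.907 for each). Fry, which tests a list against no difference, called 0 lists (adjusted p = 0.994 for each of the 7). With the block fry also called 0 lists. Its smallest adjusted p was then 0.124, for NRF2, and the rest of the 7 lay at 0.402 or higher. Adjusted over the list alone, 0 members of any list passed. Over all genes 11.8% were higher and 11.1% lower in all 3 pairs, the shares against which the list counts below are to be read. The replicate block kept the 7 lists and added 3, and with the block and an estimated correlation 0 lists passed (smallest adjusted p = 0.669).

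**Figure D1:**
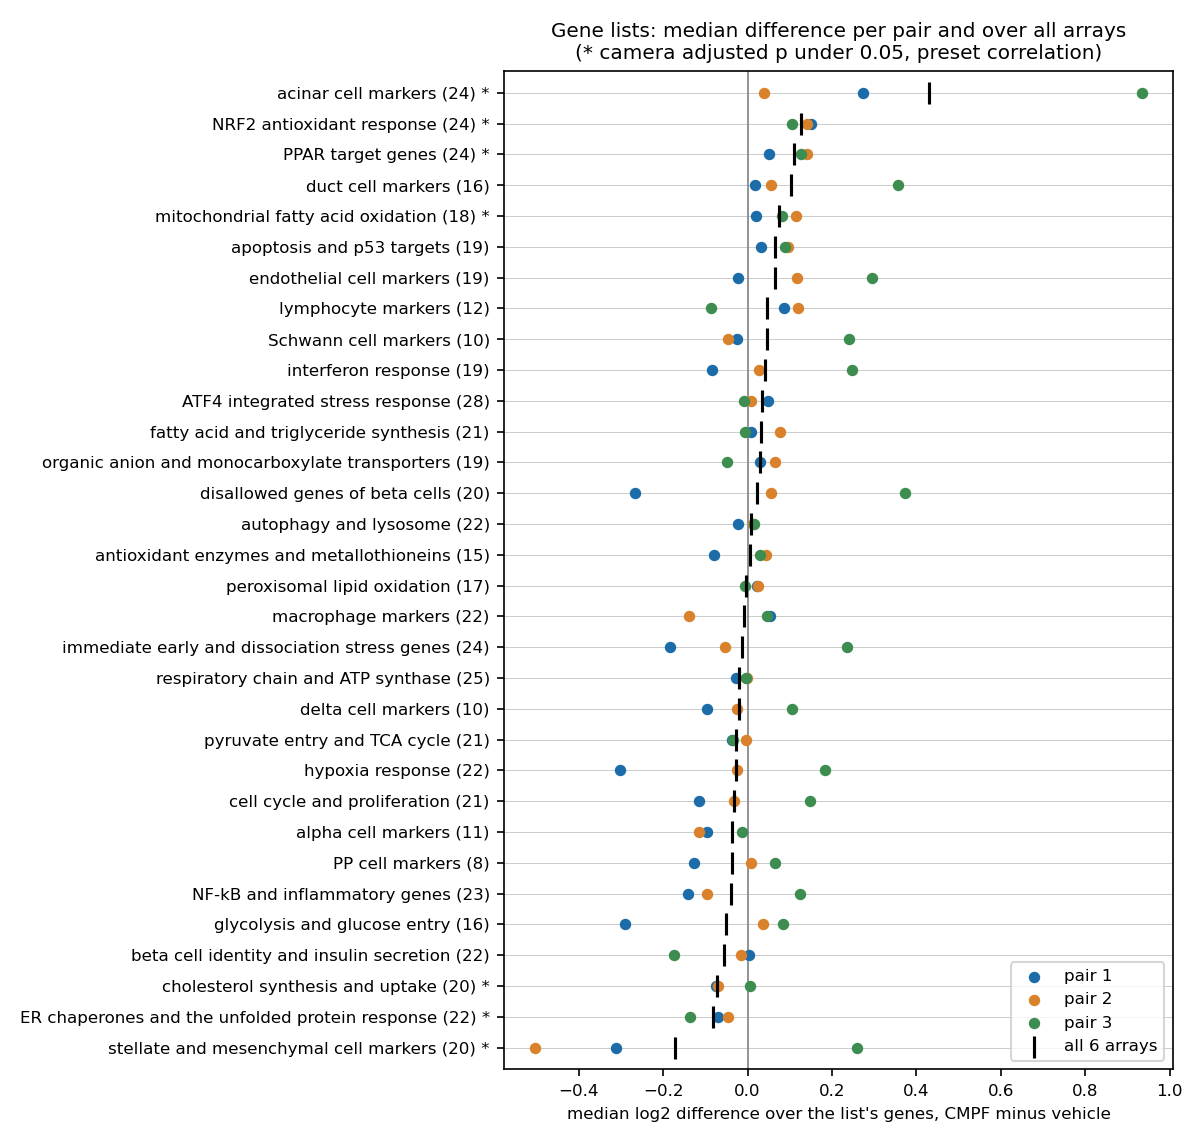
Median log2 difference (CMPF minus vehicle, x axis) over the measured genes of each of the 32 lists (y axis, number of genes in brackets); points are the 3 pairs, bars all 6 arrays, and stars mark an adjusted p under 0.05 by camera at the preset correlation. The NRF2 pairs lie close together, from 0.10 to 0.15, while the acinar pairs spread from 0.04 to 0.93.

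The NRF2 list, genes induced by oxidants and electrophiles, shifted higher with CMPF by a median of 0.13 (camera adjusted p = 7.23e-05; adjusted p = 0.907 with an estimated correlation). Of its 24 measured genes 23 had a positive difference, 16 were higher in all 3 pairs and 0 were lower in all 3. The pair medians were 0.15, 0.14 and 0.10. Gsta4, a glutathione transferase, read 7.04 ± 0.37 (SD, n = 3) with vehicle and 7.46 ± 0.25 (SD, n = 3) with CMPF, a difference of 0.42 (SE 0.206). Nqo1, a quinone reductase, read 6.47 ± 0.31 and 6.88 ± 0.51, a difference of 0.41 (SE 0.265). Ugdh, which makes UDP-glucuronate, differed by 0.20 (SE 0.116) and Pgd, of the pentose phosphate pathway, by 0.18 (SE 0.119). Hmox1, heme oxygenase, differed by 0.14 (SE 0.243). In the fit with the block the standard errors were 0.0895 for Gsta4, 0.101 for Nqo1 and 0.077 for Hmox1. None of these genes passed on its own. Acinar markers were also higher with CMPF, and with their mean as a covariate the list's median was 0.10 (adjusted p = 0.00602). The list of other antioxidant enzymes and metallothioneins was not called (median 0.0068, adjusted p = 0.730; 0.10 and called without CMPF 1), and Cat, catalase, differed by 0.32 (SE 0.298).

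PPAR target genes, which fatty acid-activated receptors induce, shifted by a median of 0.11 (adjusted p = 0.0276; adjusted p = 0.907 with an estimated correlation), with 10 of 24 higher and 1 lower in all 3 pairs. The examples with the smallest p were dim: Ucp3, a mitochondrial carrier, differed by 0.25 (SE 0.107), and the lipid droplet genes Plin4 and Plin5 each by 0.24 (SE 0.122 and 0.130). Mitochondrial fatty acid oxidation genes shifted by a median of 0.08 (adjusted p = 0.0276; adjusted p = 0.907 with an estimated correlation), with 7 of 18 higher and 0 lower in all 3 pairs. Acadvl, which oxidises very long chains, differed by 0.13 (SE 0.079), Acadm by 0.15 (SE 0.137) and Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, by 0.15 (SE 0.238). Pdk4, a PPAR target that restrains pyruvate oxidation, differed by -0.0093 (SE 0.224). With the acinar mean as a covariate both medians were 0.04 and neither list was called (adjusted p = 0.527 and 0.542). The PPAR call was also lost with both filters on dim genes (adjusted p = 0.232 and 0.0532), though the median was 0.12 under both. The PPAR median was 0.04 without vehicle 1, 0.06 without vehicle 3 and -0.02 without CMPF 2, and the oxidation median 0.06, 0.06 and 0.01, all uncalled; they were called at 0.21 and 0.11 without vehicle 2, 0.20 and 0.14 without CMPF 1, and 0.15 and 0.13 without CMPF 3. Both calls were lost without pair 2 (0.09 and 0.04) and without pair 3 (0.12 and 0.10).

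Cholesterol synthesis and uptake genes shifted lower by a median of -0.07 (adjusted p = 0.0330; adjusted p = 0.907 with an estimated correlation), with 4 of 20 lower and 2 higher in all 3 pairs. Idi1 differed by -0.23 (SE 0.144), Hmgcs1 by -0.19 (SE 0.138) and Mvd by -0.14 (SE 0.090), all enzymes of the mevalonate pathway. The call was lost without vehicle 1 (-0.06), vehicle 2 (-0.05), CMPF 2 (-0.05), CMPF 3 (-0.08), pair 1 (-0.05) or pair 2 (-0.03), and the median was -0.11 without vehicle 3. It was also lost with a second quantile normalization (-0.05, adjusted p = 0.145), probe set means (-0.05, adjusted p = 0.0665) and both filters on dim genes (adjusted p = 0.135 and 0.0532), where the median stayed at -0.07. Fatty acid and triglyceride synthesis genes were not called (median 0.03, adjusted p = 0.730). Within them Fasn, fatty acid synthase, differed by -0.07 (SE 0.171) and Acaca, acetyl-CoA carboxylase, by -0.01 (SE 0.131). Peroxisomal lipid oxidation was not called either (adjusted p = 0.884), and its median of -0.0049 and mean of 0.0091 had opposite signs.

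Genes of glucose oxidation were not called. The medians were -0.05 for glycolysis and glucose entry (adjusted p = 0.730), -0.03 for pyruvate entry and the TCA cycle (adjusted p = 0.216) and -0.02 for the respiratory chain and ATP synthase (adjusted p = 0.536). The glycolysis list was called higher without CMPF 1, at 0.21 (adjusted p = 0.00739), and lower without CMPF 3, at -0.28 (adjusted p = 0.0118). Fh1, fumarase, differed by -0.12 (SE 0.084) and was lower in all 3 pairs, as was Ndufb10 of respiratory complex I (-0.17, SE 0.082). Atp5d of the ATP synthase differed by 0.16 (SE 0.102) and was higher in all 3 pairs. Of 21 pyruvate and TCA cycle genes 6 were lower and 2 higher in all 3 pairs. Of 25 respiratory chain and ATP synthase genes 5 were lower and 3 higher.

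The hormone genes read near the highest value of any probe set, 14.73, which limits what a small difference shows. Ins2, insulin, read 14.69 ± 0.07 (SD, n = 3) with vehicle and 14.69 ± 0.01 (SD, n = 3) with CMPF, and the 95% interval of the difference ran from -0.19 to 0.20. Gcg, glucagon, differed by -0.06 (SE 0.084), Sst, somatostatin, by 0.0028 (SE 0.088) and Ppy, pancreatic polypeptide, by -0.03 (SE 0.100). Pdx1, a beta cell transcription factor, differed by -0.03 (SE 0.150), and Slc2a2, the glucose transporter, by 0.03 with a wide interval from -1.02 to 1.07. The beta cell identity list had a median of -0.06 and missed the threshold (adjusted p = 0.0956), but passed with the replicate block (adjusted p = 0.0183; adjusted p = 0.726 with the block and an estimated correlation). Its pair medians were 0.0025, -0.01 and -0.18, and it was called at -0.12 without vehicle 2, at -0.15 without CMPF 1, at -0.09 without pair 1, at -0.13 with array weights (adjusted p = 0.000508) and on ranks (adjusted p = 0.0279). The beta cell list had 2 of 22 genes lower in all 3 pairs, near the 11.1% of all genes, 1 of them G6pc2 (-0.10, SE 0.098). Genes normally kept low in beta cells were not called (median 0.02, adjusted p = 0.770), but were called higher without vehicle 2 (0.15), CMPF 1 (0.28) or pair 1 (0.20), and with array weights (0.14). Slc22a8, an organic anion transporter, read 3.90 ± 0.24 and 3.68 ± 0.05, below the lower quartile of all genes at 4.53, and its list of transporters was not called (median 0.03, adjusted p = 0.616).

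ER chaperones and unfolded protein response genes shifted lower by a median of -0.08 (adjusted p = 0.00100; adjusted p = 0.907 with an estimated correlation), with 13 of 22 lower and 0 higher in all 3 pairs. Hsp90b1, an ER chaperone, differed by -0.24 (SE 0.133), Creld2 by -0.15 (SE 0.122), Syvn1, a ubiquitin ligase of the ER, by -0.14 (SE 0.089) and Manf by -0.12 (SE 0.113). With the acinar mean as a covariate the median was -0.06 (adjusted p = 0.0496), and with a second quantile normalization -0.05 (adjusted p = 0.0375). The call was lost without vehicle 1 (-0.05), CMPF 2 (-0.04) or pair 3 (-0.07), and the median was -0.16 without vehicle 2 and -0.13 without CMPF 1. The ATF4 stress response list was not called (median 0.04, adjusted p = 0.536), and Ddit3, a stress-induced transcription factor, differed by 0.08 (SE 0.369).

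**Figure D2:**
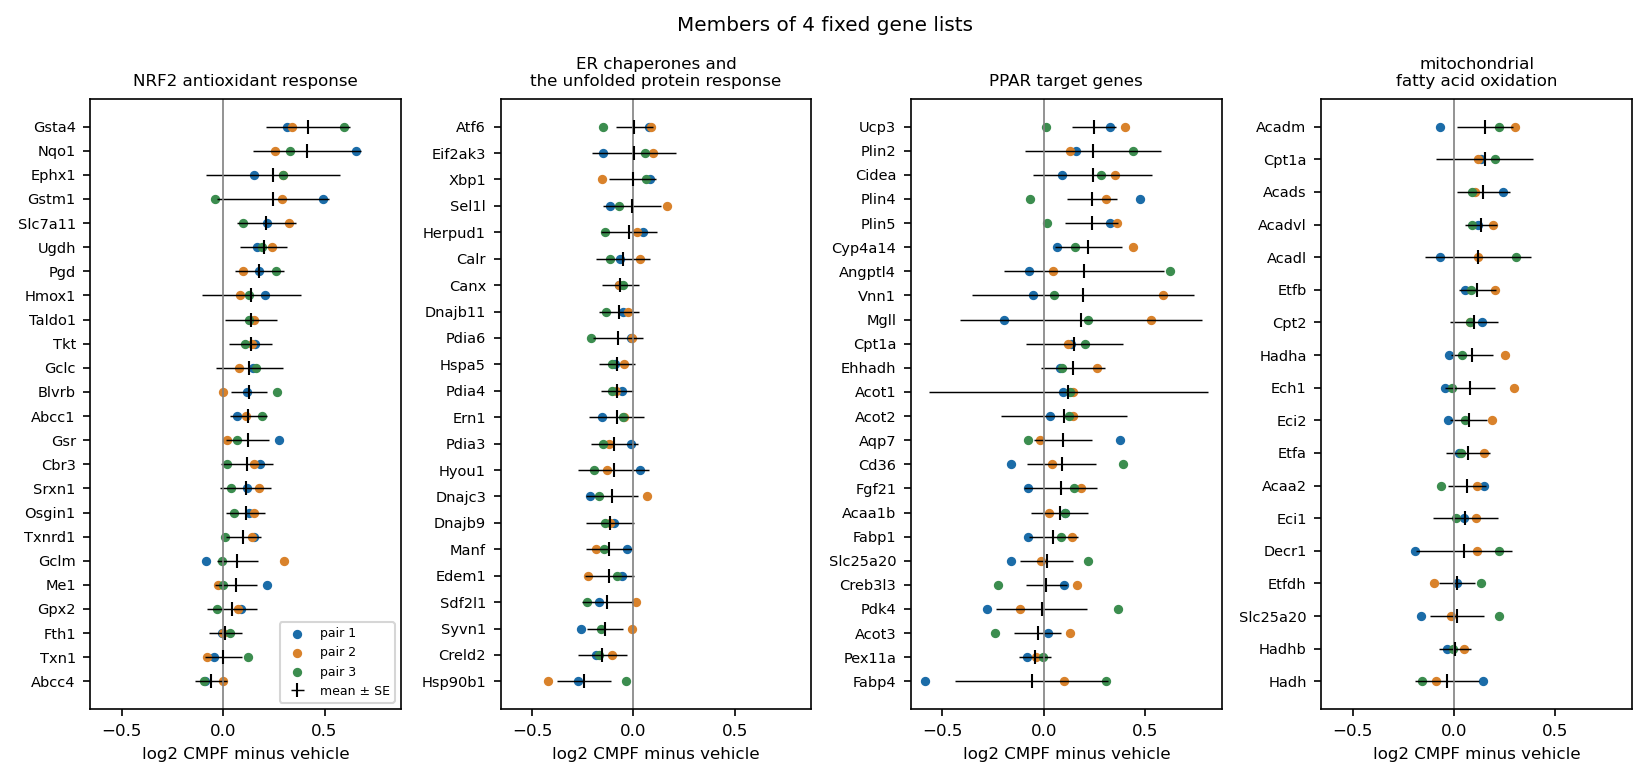
Log2 difference (CMPF minus vehicle, x axis) of each measured gene (y axis) in 4 lists; points are the 3 pairs, ticks with bars the difference of group means and its standard error (n = 3 per group). In the NRF2 panel 16 of 24 genes have all 3 points right of 0, and in the ER chaperone panel 13 of 22 have all 3 left of 0.

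The inflammatory, interferon, apoptosis, hypoxia and cell cycle lists were not called. Medians were -0.04 for NF-kB and inflammatory genes (adjusted p = 0.616), 0.04 for interferon response genes (adjusted p = 0.216), 0.06 for apoptosis and p53 targets (adjusted p = 0.211), -0.03 for the hypoxia response (adjusted p = 0.770) and -0.03 for cell cycle genes (adjusted p = 0.730). Leaving out 1 array gave calls in both directions for hypoxia, at 0.27 without CMPF 1 (adjusted p = 3.16e-05), -0.23 without vehicle 1 and -0.34 without CMPF 3. It also gave calls for apoptosis (0.17 without vehicle 2, 0.11 without CMPF 1), interferon (0.08 without vehicle 3, 0.23 without CMPF 1) and cell cycle genes (-0.14 without CMPF 3). Apoptosis and interferon genes were also called with the filter at the median level (adjusted p = 0.0362 and 0.0231) and with array weights (0.08 and 0.16) and without pair 1 (0.06 and 0.15). With the acinar covariate the NF-kB list was called lower, at -0.15 (adjusted p = 0.0116). The chemokine gene Cxcl2 differed by -1.55 (SE 0.756), with differences of -4.07, -0.05 and -0.52 in the 3 pairs. Immediate early genes (median -0.01, mean 0.015, adjusted p = 0.730) and autophagy genes (median 0.0071, mean -0.00077, adjusted p = 0.850) had medians and means of opposite sign.

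Markers of other pancreatic cell types differed between arrays. Acinar markers, from the enzyme-secreting exocrine tissue, had the largest median of any list, 0.43 (adjusted p = 0.00100; adjusted p = 0.907 with an estimated correlation), with 16 of 24 higher and 1 lower in all 3 pairs. Ctrc and Ctrb1, digestive proteases, differed by 0.64 (SE 0.445) and 0.29 (SE 0.244). The pair medians were 0.27, 0.04 and 0.93. The median was -0.07 without vehicle 3, 0.07 without CMPF 2 and 0.16 without pair 3, all uncalled, and 0.88 without vehicle 2 and 0.67 without CMPF 3, both called. Stellate and mesenchymal markers shifted lower by a median of -0.17 (adjusted p = 0.0276; adjusted p = 0.907 with an estimated correlation), but only 1 of 20 was lower in all 3 pairs, and the pair medians were -0.31, -0.50 and 0.26. The matrix gene Dcn differed by -0.55 (SE 0.326). Their median was uncalled without vehicle 3 (-0.02), CMPF 1 (-0.0097), CMPF 2 (0.02), pair 1 (-0.09) or pair 2 (-0.03), or with the acinar covariate (-0.01), array weights (-0.03, adjusted p = 0.264), probe set means (-0.11, adjusted p = 0.0603) or either filter on dim genes (-0.18 and -0.17, adjusted p = 0.0784 and 0.0532), and called without vehicle 1 (-0.31), CMPF 3 (-0.59) or pair 3 (-0.40).

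Endothelial markers missed the threshold (median 0.06, adjusted p = 0.0761) and passed with the replicate block (adjusted p = 0.00306; adjusted p = 0.702 with the block and an estimated correlation). Adjusted over the list alone, 4 endothelial genes passed with the block, all below the median level of all genes. Given with standard errors from the block, they were Tek (0.37, SE 0.076), Sox18 (0.40, SE 0.101), Vwf (0.31, SE 0.082) and Tie1 (0.29, SE 0.080). Vwf was chosen after its values were seen. Without the block the list was called when vehicle 2 (0.08), vehicle 3 (0.14) or CMPF 1 (0.28) was left out, without pair 1 (0.19), with array weights (0.13) and with median centring (0.06). Duct markers had a median of 0.10 (adjusted p = 0.734) and passed with the block (adjusted p = 0.0220; adjusted p = 0.726 with the block and an estimated correlation). With the acinar covariate the duct median was -0.09 and called lower (adjusted p = 0.0234), and without vehicle 2 it was 0.31 and called higher. The other lists were not called, with medians of -0.0078 for macrophages (adjusted p = 0.730), 0.05 for lymphocytes (adjusted p = 0.403), 0.04 for Schwann cells (adjusted p = 0.0761), -0.04 for alpha cells (adjusted p = 0.603), -0.02 for delta cells (adjusted p = 0.616) and -0.04 for PP cells (adjusted p = 0.884). Macrophage markers were called without CMPF 3 (-0.08), and Schwann cell markers without vehicle 3 (0.12), CMPF 1 (0.12), CMPF 2 (0.16), pair 1 (0.11) or pair 2 (0.14), and with the acinar covariate (0.13), array weights (0.11) or the filter at the 25th percentile (0.04).

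**Figure D3:**
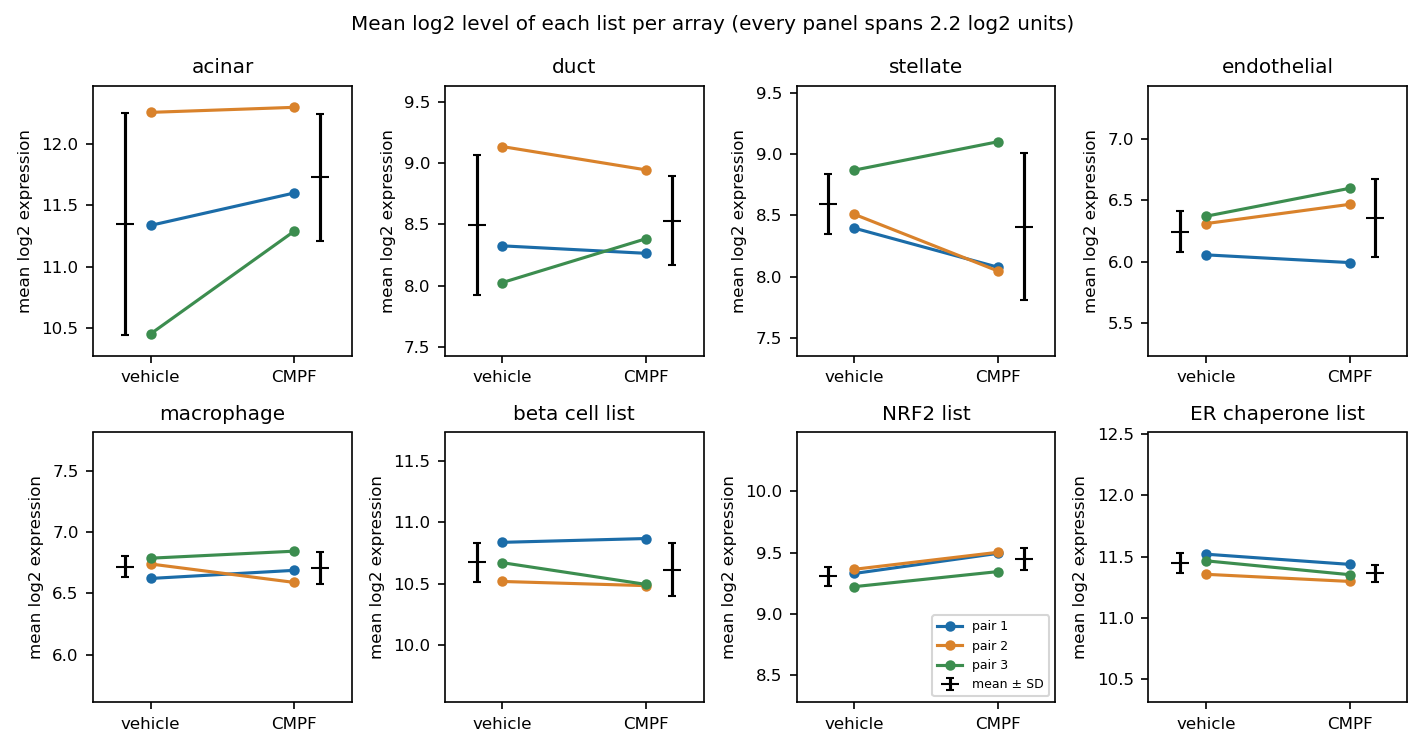
Mean log2 level of 8 lists (y axis, every panel 2.2 log2 units high) on each array; lines join the vehicle and CMPF array of a pair, and black marks give the mean and SD of each group (n = 3). The acinar mean runs from 10.45 to 12.26 among the vehicle arrays and from 11.29 to 12.30 among the CMPF arrays.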

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

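The settings that leave out a pair, or join the block with an estimated correlation or fry, were chosen after seeing the data. The count of genes past the threshold was 0, in both directions, under each setting tried. The count of called lists was 7 and stayed between 5 and 8 with median centring, a second quantile normalization, probe set means, either filter on dim genes, ranks or the acinar covariate. The lists behind that count changed. Of the 7 lists, 3 stayed called with the acinar covariate and 4 with either filter on dim genes. The count was 10 with the replicate block. It was 12 with array weights, 0 with an estimated correlation, 0 with fry, 0 with the block and an estimated correlation, and 0 with the block and fry. Leaving out 1 array gave from 2 (without CMPF 2) to 15 (without CMPF 1), with 4 without vehicle 1 and 11 without vehicle 2. Leaving out both arrays of a pair gave 13 for pair 1, 5 for pair 2 and 4 for pair 3, among them duct markers (0.14) without pair 2 and cell cycle genes (-0.09) without pair 3. Of the 7 lists only NRF2 was called without each pair. The block changed no other call than those of the endothelial, beta cell and duct lists. The NRF2 list was called under 20 of 24 alternatives (adjusted p from 5.37e-09 to 0.994) and in all 6 leave-outs. All settings that kept this call used camera at the preset correlation of 0.01. It was lost with an estimated correlation and with fry, each with and without the block. The 20 therefore do not vary the setting on which the call depends. Called medians that changed sign, or medians called with the other sign, were acinar -0.0076 and duct -0.094 with the acinar covariate, hypoxia 0.074 and immediate early genes 0.099 without pair 1, PPAR targets -0.015 without CMPF 2, and 4 lists with 1 array left out. Over those leave-outs the medians ran from -0.070 (without vehicle 3) to 0.881 for acinar, from -0.279 to 0.215 (without CMPF 1) for glycolysis, from -0.336 to 0.268 (without CMPF 1) for hypoxia and from -0.593 to 0.024 (without CMPF 2) for stellate markers. The acinar covariate removes acinar differences by construction. A fit without 1 array keeps that array's partner, so differences between pairs enter its comparison of CMPF with vehicle. The pair medians themselves ran only from -0.30 to 0.18 for hypoxia and from -0.29 to 0.08 for glycolysis. How much of the sign changes broken pairs account for was not tested. The direction given by camera or fry, which can differ from the sign of the median, flipped for 97 of 767 list values. PPAR targets without CMPF 2 and immediate early genes without pair 1 were not among these. The difference flipped sign for 98 of 2680 values of named genes, none called in any setting. Trend and robust priors do not enter camera, so they test nothing for lists. A fit without 1 array leaves 2 in a group and assumes that they vary like the other group.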

Other observations

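The genes in the first 2 paragraphs were chosen after their values were seen, from a larger number looked up, and none passed the threshold. Cyp1a1, a xenobiotic-metabolising cytochrome P450, had the largest positive difference: 6.11 ± 0.35 (SD, n = 3) with vehicle and 6.99 ± 0.45 with CMPF, a difference of 0.87 (SE 0.256, or 0.0995 with the block), with pair differences of 0.67, 1.07 and 0.87. Cyp1b1, of the same family, differed by 0.49 (SE 0.154), and both genes had no overlap between groups. The glutathione transferases Gsta2 and Gsta3, outside the fixed lists, differed by 0.51 (SE 0.195) and 0.54 (SE 0.522) and were higher in 3 of 3 pairs, though related transferases can share probes. Ptgr1, a reductase of lipid enones, differed by 0.33 (SE 0.366), again higher in 3 of 3 pairs.

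Of the 21 genes at least 1.5-fold apart, 15 were lower with CMPF. Saa1, an acute-phase protein gene, differed by -1.67 (SE 0.772), with pair differences of -3.14, -0.38 and -1.50, and Saa2 by -0.81 (SE 0.350). Saa3 differed by -0.30 (SE 0.251) and was also lower in 3 of 3 pairs. Serpina1c (-2.01, SE 1.41), Hpx (-1.40, SE 0.945) and Alb (-0.86, SE 0.669) were not lower in pair 2, with differences there of 0.00032, 0.81 and 0.19. Serpina1 and Saa genes are families of near-identical copies, so the values of single members are uncertain. Onecut2, a transcription factor, differed by -0.83 (SE 0.242) and was lower in 3 of 3 pairs. Among the 10092 probe sets without a single gene name, limma called 0 (smallest adjusted p = 0.999), and 226 had an unadjusted p under 0.05.

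In the following, the tests of single arrays, of the endocrine share and of exocrine carry-over were chosen after the result was seen. The real grouping gave 7 called lists; 3 against 3 arrays allow 10 splits, too few for a share under 0.05, and 7 of the 10 gave as many, with 16 as the highest other. The 6 splits that keep a pair together gave 8 to 16 lists, which points to the pairs as a structure of the samples. Among the 4 splits that part all 3 pairs, the real one gave 7 lists and the others 2 to 6. Genes with an unadjusted limma p under 0.05 did not rank the same way. They numbered 205 for the real split and 594, 182 and 210 for the others. A first rank among 4 splits is too common by chance to set the real grouping apart. For genes past the adjusted threshold the real count was 0 and the highest other 0. No split can give fewer than 0, so the comparison of that count tests nothing.

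The NRF2 shift (median 0.1257) was set against more exocrine RNA in the CMPF arrays and against a single deciding array. With the acinar mean as a covariate the median was 0.10 and the list was still called (adjusted p = 0.00602), which argues against exocrine RNA as the whole cause. The lowest median without 1 array was 0.10, without vehicle 3, which argues against 1 array. Correlated genes remain open. The camera call was lost with the estimated correlation, 0.071 against the preset 0.01. That setting also lowered the degrees of freedom to 4. The adjusted p of 0.907 was the same for cholesterol genes (estimated correlation 0.026) and acinar markers (0.784). The loss therefore does not show how much of the shift correlation accounts for. An NRF2 response to CMPF is a hypothesis that these arrays leave open.

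Acinar markers lay higher with CMPF. A lower share of endocrine cells alone would raise markers of every other type alike. The acinar median exceeded the stellate median by 0.59, 0.54 and 0.68 in the 3 pairs (mean 0.60, SD 0.068). Acinar and stellate markers had the highest and lowest medians of all lists, 0.43 and -0.17, so a positive difference was favoured in advance. The test therefore cannot decide on a common rise. In pair 3 the duct (0.36), endothelial (0.29) and Schwann (0.24) medians rose too, and the beta cell median was -0.18. Macrophage (0.05) and lymphocyte (-0.09) medians did not follow there. In pair 1 the duct, endothelial and Schwann medians were 0.02, -0.02 and -0.03, with acinar at 0.27. Stellate markers themselves moved by -0.31, -0.50 and 0.26, so a lower endocrine share beside a separate fall of stellate markers cannot be excluded. Uneven carry-over of exocrine tissue stays open. The acinar mean differed by 0.26, 0.04 and 0.84 within the pairs, and the mean of 0.38 lay within their SD of 0.41, so carry-over that happened to favour CMPF cannot be told apart from an effect of CMPF on acinar cells with 3 pairs.

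Cyp1a1 and Cyp1b1 are targets of the aryl hydrocarbon receptor, and a candidate explanation is activation of that receptor. Of 12 targets listed, 7 had not been looked at before and were measured. Their median was 0.06, at percentile 82.86 of 10000 random lists matched on mean expression, between the bounds set beforehand for and against activation. Cyp2s1 was higher in 3 of 3 pairs (0.32, SE 0.168), while Scin was lower in 3 of 3 (-0.25, SE 0.145). Whether the receptor was active cannot be told apart from chance with 7 genes, 3 of them below the lower quartile of all genes' levels.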
